A study of Mus musculus with 2 samples.

How the data were processed

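Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the DNA sites of KLF6, a zinc finger transcription factor of the Krüppel-like family, in a mouse hepatocellular carcinoma (HCC) cell line. Per the labels, the cells carried an expression plasmid for full-length KLF6 fused to the V5 epitope, the precipitation used an antibody against V5, and the control was DNA of the same kind of cells taken without precipitation (input). There were 2 samples, 1 of precipitated and 1 of input DNA. Per the labels, each came from replicate experiments, the first of which was sequenced in 2 runs. No precipitation from cells without the tagged protein was among the samples, so each list rests on a comparison with input DNA alone.

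The authors deposited 2 annotated lists of binding sites, each from a comparison of KLF6-ChIP with input. The first list pools both runs of experiment 1, and the second list holds experiment 2. Sites were thus called per experiment and not per sequencing run. MACS 1.3.6 and the mouse build mm9 are named in the submitters' processing notes, which do not say for which step each was used. The aligner, the parameters and the read totals are not given in the sources used here, so the depth of each library is unknown and no limit of detection can be derived from it. Coordinates are printed as the deposited lists give them.

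The deposited lists give, per the file headers, a tag count for each site, which is a whole number and not normalised. Which library the tags were counted in is not stated. The score of a site is, per the file headers, 10 times the −log10 of the caller's p-value. Every deposited score was above 50, which corresponds to a p-value of 1e-05. The fold enrichment is, per the file headers, a ratio, and it is taken here as ChIP over the background the caller expected. The false discovery rate (FDR) is, per the file headers, a percent, with 100% as its highest value. All 4 are the authors' own values, computed by their peak caller within a list, and were used to describe, rank and filter sites within that list. Fold and score also served to compare shared with unshared sites and to correlate the lists across shared sites. Tags and fold together gave an implied background. The lists also assign each site to an Ensembl gene, with its description, and give the distance of the site's summit to the start of that gene. The distance equalled the summit minus the gene start, signed by strand, at each site of both lists. A gene symbol was given for 307 of the 742 sites of experiment 1 and 384 of the 901 sites of experiment 2. Of the distinct symbols, 271 of 276 and 355 of 364 matched a table of RefSeq genes of assembly GRCm38.p6. That assembly is not the build of the lists, so the table served only for gene names, gene types and the order of genes along chromosomes, and none of its coordinates are printed. At 2 sites of experiment 1, at Hist2h4 and Rbm8a, and 1 site of experiment 2, at Gm5138, the table placed the symbol on another chromosome than the site, and these were left out of the tests of neighbouring genes.

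Sites were called shared when at least 1 bp of a site in one list overlapped a site in the other. The number of shared sites was compared with 1000 random placements, as a one-sided test. In these, each site of experiment 1 was moved uniformly within the span that sites and their assigned genes cover on its chromosome. The same number was also compared, one-sided, with 1000 placements in which each site of experiment 1 was moved by 10 to 100 kb. Fold enrichments of shared and unshared sites were compared on the log2 scale by two-sided permutation tests with 100000 resamples. Pearson's r and Spearman's rank correlation across shared sites were computed on log2 values of fold or score, with permutation p-values from as many resamples. Shares of sites near gene starts (summit within 1 kb) have exact Clopper-Pearson intervals at 95%, which cover counting error only, and were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 8 tests. Each of 19 gene lists was tested by Fisher's exact test against all 49980 genes of the reference table, with adjustment over the lists. Gene length and the size of intergenic regions were not corrected for. The lists covered reported KLF6 targets, the KLF and SP families, autophagy, cell cycle, p53 and apoptosis, TGF-beta and matrix, hepatocyte identity, lipid and glucose metabolism, liver cancer, stress responses, adhesion and angiogenesis, markers of stellate, endothelial, immune, bile duct and of neuronal, muscle and germline cells, olfactory receptors, ribosomal proteins and histones. Site counts per chromosome were compared with gene numbers by a chi-square statistic with 100000 simulated draws. In each of these tests the units were sites or genes, not replicate experiments. With 1 sample per group and no values per library in the lists, no test across libraries could be made.

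The groups, tests, gene lists, most alternatives and the rule for sites named in the text were fixed before the data were examined. The rule took the 10 shared sites with the best mean rank by fold enrichment, up to 3 members of each gene list with a shared site or 2 with a site in 1 list, every reported KLF6 target with a site, Klf6, the 3 strongest sites found in 1 list only, and genes with more than 1 shared site, of which there was 1, counted from experiment 2. Of the 10 leading shared sites, 1 is not described. Other sites are named where the text says that they were picked after their values were seen. Alternatives covered the overlap required, the 50% of sites with the higher score, 1 list alone, 5 kb in place of 1 kb, and the caller's score in place of the fold. An implied background was computed for each site as tags divided by fold, per kb of site. It depends on how the caller computed the fold, which is not given in the sources used here. The overlap and gene list steps were tested on simulated data of the same size. They recovered 100 of 100 planted shared sites, found 1 overlap between random lists and called 0 of 19 lists for random genes. The random genes were drawn evenly from all genes of the reference table. They therefore cannot show false calls that come from the choice of background, gene length or intergenic size. A search of the sites for KLF or SP sequence motifs was planned but left out, because no genome sequence of build mm9 was at hand. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.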

Results

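KLF6 binding sites were mapped in a mouse HCC cell line that carried a plasmid for V5-tagged KLF6, with antibody against V5 and input DNA as the control. The design had 1 precipitated and 1 input sample, and the sites were called in 2 experiments, the first of which pooled 2 sequencing runs. Experiment 1 gave 742 sites with a median width of 554 bp, and experiment 2 gave 901 sites with a median width of 296 bp. Tags per site had a median of 21 in experiment 1 (range 14 to 583) and 11 in experiment 2 (range 9 to 1221). The median fold enrichment was 7.17 in experiment 1 and 10.0 in experiment 2, and it reached 75.3 and 66.9. The authors' FDR was at its highest value of 100% for 584 sites of experiment 1 (78.7%) and 872 sites of experiment 2 (96.8%). It was 5% or lower for 61 sites of experiment 1 and for 0 sites of experiment 2, where the lowest value was 20%. The read totals behind these lists are unknown, so differences in the number of sites between the lists cannot be set against depth.

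The comparison of the experiments asked which sites were found in both. The strongest shared site lay on chromosome 14 from 103863273 to 103864394 (coordinates of experiment 1, mm9), 48.5 kb upstream of the gene for sciellin, a protein of the cornified cell envelope. It was enriched 75.3-fold in experiment 1 and 60.5-fold in experiment 2. Other leading shared sites lay 47.8 kb upstream of Crtam, which encodes an adhesion receptor of lymphocytes (chromosome 9 from 40860300 to 40860911, 43.0-fold and 49.4-fold), and inside Npy5r, a neuropeptide Y receptor gene (chromosome 8 from 69210088 to 69210907, 42.5-fold and 44.5-fold). The site with the highest score in both lists was assigned to a U6 spliceosomal RNA gene 25 kb away on chromosome 12 (70712006 to 70712936), with 525 tags at 35.9-fold in experiment 1 and 254 tags at 47.4-fold in experiment 2.

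Other sites among the 10 with the best mean rank were of the same order of enrichment. A site 3.45 kb upstream of a U1 spliceosomal RNA gene on chromosome 7 (85058388 to 85058922) reached 60.6-fold and 36.9-fold. A site inside 4930452B06Rik on chromosome 14 (9438736 to 9439600) reached 43.7-fold and 31.3-fold. A site on chromosome 13 (21584365 to 21585142), 2.33 kb upstream of ENSMUSG00000035253, had the highest fold of experiment 2, at 66.9, against 27.8 in experiment 1. A site on chromosome 1 (53538633 to 53539374) near ENSMUSG00000041365 reached 29.3-fold and 34.0-fold, and one 311 kb upstream of Cntnap5b, also on chromosome 1 (101357970 to 101358590), reached 30.0-fold and 23.9-fold.

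In all, 109 sites of experiment 1 (14.7%, interval 12.2 to 17.4) overlapped 112 sites of experiment 2 (12.4%, interval 10.3 to 14.8). Random placement gave a mean of 0.264 overlaps and at most 3 in 1000 placements (one-sided permutation of positions, p = 0.001, the smallest it can give). The observed number was 413 times that mean. Moving sites by 10 to 100 kb gave a mean of 0.244 and again at most 3 (permutation of positions, p = 0.001). The summits of the paired sites lay a median of 10.5 bp apart, and both lists assigned the same gene at each of the 109. Counted from experiment 2, 1 gene had more than 1 shared site. It was 3110070M22Rik on chromosome 13, where 4 sites of 11.2-fold to 20.7-fold overlapped a single site of experiment 1 (120280545 to 120283626, 13.3-fold). Where at least 50% of each site had to be in common, 47 sites were shared. Of the 61 sites of experiment 1 with an FDR of 5% or lower, 42 were shared (68.9%). The FDR of a shared site was often high all the same. It was 100% in experiment 2 for 85 of the 109, among them the site near sciellin.

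Sharing followed the strength of the call. Among the 50 sites with the highest score, 43 were shared in each list (86.0%, interval 73.3 to 94.2). The next 50 held 22 shared sites in experiment 1 and 20 in experiment 2, and ranks 251 to 300 held 1 and 7.

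**Figure D1:**
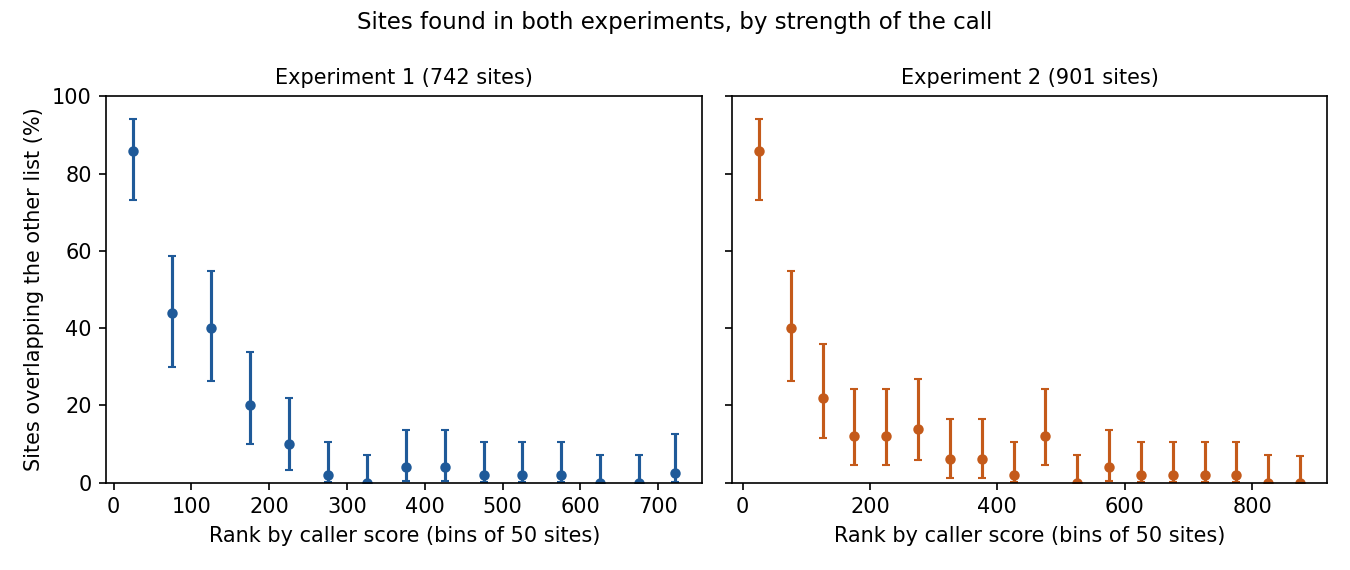
Share of sites that overlap a site of the other experiment (y axis, percent) for bins of 50 sites ranked by the caller's score (x axis), experiment 1 on the left and experiment 2 on the right. Points are shares and bars are exact 95% intervals, and the first bin stands at 86.0% in both lists.

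Shared sites were the more enriched ones in both experiments. In experiment 1 the median fold was 15.3 at the 109 shared sites and 6.66 at the 633 unshared sites. The difference of mean log2 fold was 1.16 (SD 0.73 among shared and 0.47 among unshared sites, permutation p = 1e-05, the smallest the permutations can give). In experiment 2 the medians were 14.3 at 112 shared and 9.58 at 789 unshared sites, with a log2 difference of 0.64 (SD 0.72 and 0.33, permutation p = 1e-05). The strongest sites found only in experiment 1 lay 603 bp upstream of Ctnna3, an alpha-catenin gene (chromosome 10 from 62891987 to 62892467, 23.3-fold), and 8.29 kb upstream of Rnase4, a ribonuclease gene (chromosome 14 from 51702164 to 51702980, 23.3-fold). The next, of 22.7-fold, lay on chromosome 7 from 100234695 to 100235334 near a gene for an uncharacterised protein. The strongest sites found only in experiment 2 were a neighbouring pair on chromosome 19 upstream of Csf2ra, a cytokine receptor gene (61339848 to 61340154, 35.8 kb away, at 23.9-fold and 61340193 to 61340432, 36.1 kb away, at 19.1-fold), and a site inside Tmx3 on chromosome 18 (90683818 to 90684136, 15.9-fold). Absence from one list was not tested against the depth of that list.

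Across the 109 shared sites, the log2 fold in experiment 1 and the log2 fold in experiment 2 rose together (Pearson r = 0.654, Spearman rank correlation = 0.558, permutation p = 1e-05 for each). The log2 scores gave r = 0.718 and a rank correlation of 0.573 (permutation p = 1e-05 for each). Without the sites in the top 5% of fold of either list, 101 sites gave r = 0.494 and a rank correlation of 0.45 (permutation p = 1e-05 for each). These correlations run across sites, which are not independent replicates, and only across sites strong enough to be called in both lists. Hist1h4h, a replication-dependent histone H4 gene, is an example of close values, with a site 13.3 kb upstream (chromosome 13 from 23609298 to 23610034) at 25.1-fold and 24.1-fold.

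**Figure D2:**
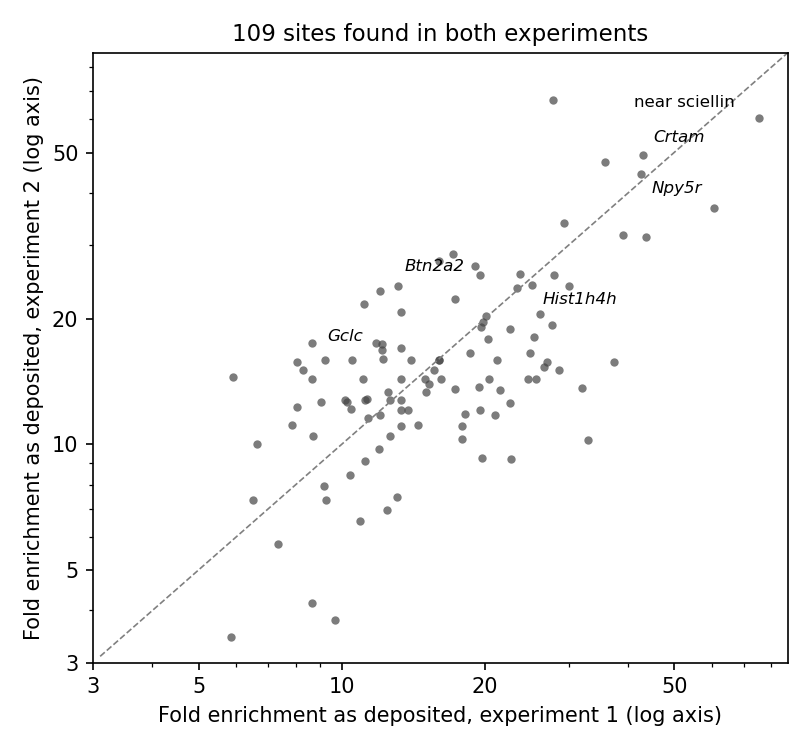
Fold enrichment as deposited for each of the 109 shared sites in experiment 1 (x axis, log scale) and experiment 2 (y axis, log scale), with the line of equal values dashed. The site near sciellin, at 75.3-fold and 60.5-fold, lies at the upper right.

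The position of sites relative to genes was then compared. Sites lay mostly far from the start of the assigned gene, but the distance expected of random positions was not computed. The median distance was 53633 bp in experiment 1 and 50407 bp in experiment 2. Inside the assigned gene lay 99 sites (13.3%) and 166 sites (18.4%). Sites inside a gene other than the assigned one are not in these counts. Of the 1531 distinct sites in either list, 39 (2.55%, interval 1.82 to 3.47) lay within 1 kb of the start of the assigned gene. They were 29 sites of experiment 1 (3.91%) and 16 sites of experiment 2 (1.78%). Within 5 kb, 87 sites of experiment 1 (11.7%) and 96 of experiment 2 (10.7%) were found. Genes with a site within 1 kb of the start in experiment 1, picked after their values were seen, included Polr3e, a subunit of RNA polymerase III (275 bp upstream, 15.7-fold), Ndufs7, a subunit of respiratory complex I (109 bp upstream, 8.06-fold), and Sacm1l, a phosphoinositide phosphatase (299 bp upstream, 9.62-fold). All 3 sites were found in experiment 1 alone, with an FDR of 17.2% at Polr3e and 100% at Ndufs7 and Sacm1l, and all 3 genes had a tRNA gene among their 5 neighbours on either side.

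Shared sites lay close to gene starts more often than unshared sites in experiment 2. There, 6 of 112 shared sites and 10 of 789 unshared sites lay within 1 kb (5.36% and 1.27%, Fisher's exact test, adjusted p = 0.0362), and 22 and 74 lay within 5 kb (19.6% and 9.38%, adjusted p = 0.0215). All 6 of these shared sites within 1 kb were assigned to features without a gene symbol, a U1 spliceosomal RNA gene and others without a description. In experiment 1 the shares were 5.5% and 3.63% within 1 kb (adjusted exact p = 0.668) and 18.3% and 10.6% within 5 kb (adjusted exact p = 0.0649). Whether the lists differ in this was not tested. Small RNA genes were assigned to 97 sites of experiment 1 (13.1%) and 113 sites of experiment 2 (12.5%). U6 genes made up 37 and 42 of these, SNORA17 genes 8 and 22, and U1 genes 18 and 8. Shared and unshared sites did not pass the test for a difference in this share in either list (adjusted exact p = 0.879 in both). What random positions would give was not computed, either for small RNA genes or for nearness to gene starts. No preference of the sites for or against such places can be read from these shares.

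The gene lists asked whether sites gathered near genes of known functions. At least 255 of the 271 matched genes of experiment 1 and 343 of the 355 of experiment 2 were protein-coding. Expected numbers taken from all 49980 genes are therefore too low for lists of protein-coding genes. Against the protein-coding genes alone, 0 lists passed the adjusted threshold. Of the 25 reported KLF6 targets, 1 had a site, Asah1, which encodes acid ceramidase (expected 0.281, adjusted exact p = 0.603). That site lay downstream, 54.1 kb from the gene start, at 8.76-fold in experiment 2 alone. The adhesion and angiogenesis list had the lowest p-value, with 3 of 31 members against 0.348 expected (Fisher's exact test, p = 0.00501, adjusted exact p = 0.0951). Its members were Vegfc, a lymphatic growth factor gene with a site inside it (10.8-fold), Twist1, a transcription factor gene with a site 163 kb away (11.2-fold), and Cldn1, a tight junction gene picked after the counts were seen. All 3 had sites in experiment 2 alone, and the sites at Vegfc and Twist1 had an FDR of 100%. Experiment 2 alone gave this list an adjusted exact p of 0.0262, and a background of the 21900 protein-coding genes gave 0.75.

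No list of the 19 passed the adjusted threshold by Fisher's exact test, and 3 had an unadjusted p under 0.05. Olfactory receptor genes were the second of these, with 26 of 1429 members against 16 expected (exact p = 0.0153, adjusted exact p = 0.145). Among them Olfr180 (11.8-fold and 17.5-fold) and Olfr1168 (10.5-fold and 15.9-fold) had shared sites. When only sites within 5 kb of the start were counted, 15 olfactory receptor genes were left and the adjusted exact p against all genes was 2.04e-08. All 26 against the protein-coding genes gave an adjusted exact p of 1, but the 15 were not tested against that background. The third was the KLF and SP family, with Klf6 and, picked after the counts were seen, Sp4 (2 of 26 members, exact p = 0.0342, adjusted exact p = 0.217). It missed the threshold against the protein-coding genes too. Klf6 counted through the sites of experiment 1 examined below and a site of experiment 2 that lay 191 kb upstream. Stress response genes were represented by Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, with a shared site 33.6 kb upstream (12.1-fold and 16.8-fold; 1 of 32 members, adjusted exact p = 0.603). Histone genes had 2 of 71 members with a site, Hist1h4h and, picked after the counts were seen, Hist2h4 (adjusted exact p = 0.601). The site assigned to Hist2h4 lay on chromosome 6, where the reference table does not place that symbol.

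The other lists held few sites or none. TGF-beta genes had sites at Smad2 and Smad7 (10.2-fold and 9.27-fold, 2 of 35 members, adjusted exact p = 0.279), both in experiment 2 alone. Autophagy had 1 of 38 members, Pik3c3, which encodes a lipid kinase needed for autophagosomes, with a site 741 kb from the gene (adjusted exact p = 0.603). Genes of p53 and apoptosis had 1 of 34 members, Pmaip1, a proapoptotic BH3-only gene (10.7-fold, adjusted exact p = 0.603). The endothelial list had 1 of 11 members, Cdh5 (6.66-fold, adjusted exact p = 0.444). The list of neuronal, muscle and germline markers had 1 of 26 members, Tnp1 (adjusted exact p = 0.603), and the ribosomal proteins had 1 of 80, Rpl31 (adjusted exact p = 0.942). The 7 lists of cell cycle, hepatocyte identity, lipid and glucose metabolism, liver cancer, stellate, immune and bile duct genes had 0 members with a symbol-bearing site (adjusted exact p = 1 each). Of the sites, 41.4% in experiment 1 and 42.6% in experiment 2 had a gene symbol, so these counts are lower limits.

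The Klf6 gene itself was examined because the cells carried a KLF6 plasmid. Experiment 1 had 3 sites inside the gene, which spans 5860735 to 5869639 on chromosome 13. The site from 5863651 to 5864920 had 583 tags, the most of any site of experiment 1, at 3.94-fold with an FDR of 1.59%. The site from 5860546 to 5861201, which covers the gene start, had 194 tags at 6.01-fold with an FDR of 1.64%. The site from 5865504 to 5866305 had 137 tags at 7.83-fold with an FDR of 47.5%. Experiment 2 had no site inside the gene, and its nearest site assigned to Klf6 lay 191 kb upstream (11 tags, 9.36-fold). The tags per fold implied a background of 117, 49.3 and 21.8 tags per kb at the 3 sites, each above the 95th percentile of experiment 1, which was 10.6. Exon positions in build mm9 were not at hand, so the sites could not be placed on exons or introns.

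**Figure D3:**
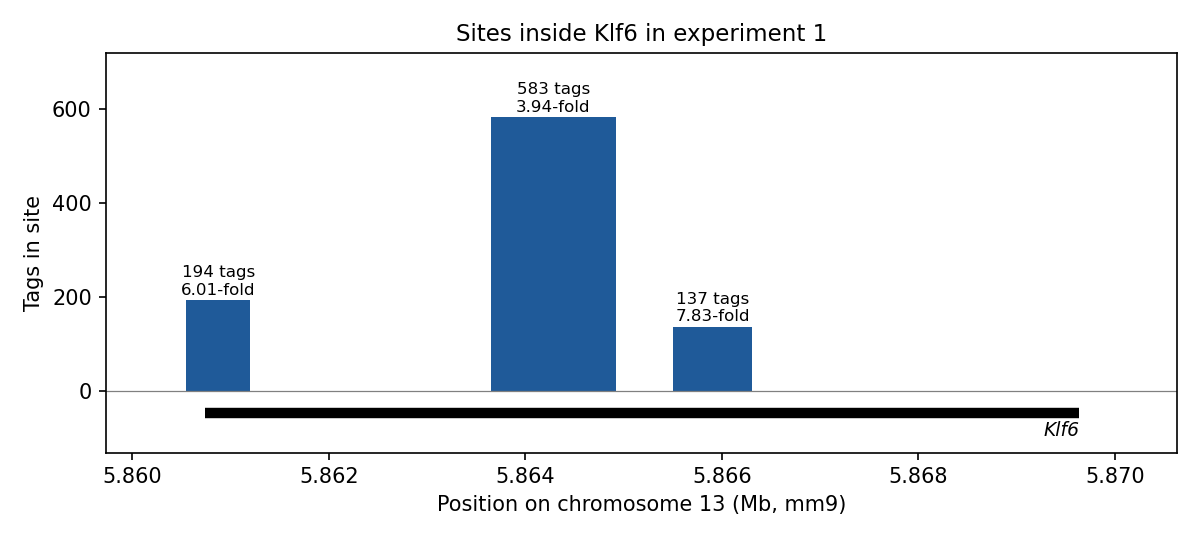
Tags (y axis) of the 3 sites of experiment 1 inside Klf6, drawn to scale along chromosome 13 in Mb of mm9 (x axis), with the gene as a black bar. The labels give tags and fold, and the site with 583 tags has the lowest fold, 3.94.

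Sites were spread unevenly over the 20 chromosomes that carried them. Chromosome 6 had 75 sites in experiment 1 and 71 in experiment 2, which is 1.75 and 1.36 times the number expected from its genes, and chromosome 3 had 63 and 71 (1.71 and 1.59 times). Chromosome 7 had 23 and 21 sites, 0.369 and 0.278 times the expected number. The chi-square statistic against gene numbers was 88.3 in experiment 1 and 87.3 in experiment 2 (19 degrees of freedom, simulated p = 1e-05 for each, the smallest the draws can give). Against the span that sites and genes cover, an expectation chosen after seeing the data, it was 55.5 and 51.1 (simulated estimates of the exact multinomial p = 5e-05 and 7e-05). Single chromosomes were not tested.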

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

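Of 100 alternatives, 68 were fixed before the data were examined and 32, which concern the implied background, the background genes, members named by description, the Klf6 locus by experiment and the span of chromosomes, were chosen after seeing the data. Of these, 72 concerned single gene lists, none of which had passed the threshold. In 69 of the 72 the list still missed it, in 26 of them with 0 members left, so that neither count nor direction held, and in 3 it passed. Of the other 28, 19 kept their direction and side of the threshold, their count within 1.5 times or their share within the 95% interval, and 9 moved. The number of shared sites was 47 where 50% of each site had to be in common, which the wider sites of experiment 1 make harder to meet. It was 93 among the higher-scoring 50% of sites and 95 without the 5% of sites with the highest implied background. The share of sites near gene starts was 2.55% within 1 kb, 10.5% within 5 kb, as the wider window implies, and 3.74% among the higher-scoring 50% of sites, where the cause was not tested. Leaving out an experiment, it ranged from 1.78% to 3.91%. The number of gene lists past the threshold was 0 in the reported analysis, 1 with sites within 5 kb (olfactory receptors), 1 with members added by description, where adhesion and angiogenesis genes gained Cdh2 (adjusted exact p = 0.00758), and from 0 to 1 with an experiment left out. Only 4 members of the lists were added by description, and no genes outside the lists. List counts could thus only rise, and this alternative cannot show that sites gathered near such genes. Beyond that, the causes of these shifts were not tested. The number of sites inside Klf6 ranged from 0 to 3 with an experiment left out, since all 3 were sites of experiment 1. An FDR of 5% or lower gave no count of shared sites because experiment 2 had 0 such sites, and the KLF or SP sequence search within windows around the summits was not run for lack of a genome. No paired analysis was possible because each group had 1 sample and the lists carry no values per library. The unknown depth limits any reading of sites found in 1 list only.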

Other observations

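The placements of moved sites, used below against chance overlap, were fixed before the data were examined. The tests of the Klf6 sites and those of the overlap by implied background were chosen only after the result was seen. So were the tests of tRNA genes near sites of experiment 1. For the tests on tRNA genes at shared sites, with and without chromosome 13, the expected outcomes were set before the tests were run. The same held for the tests on snoRNA genes.

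A stretch of 2.5 Mb on chromosome 13, picked after the sites were seen, held 6 shared sites, the first with its summit at 21584762 and the last at 23609590, among 9 sites of experiment 1. From one end to the other, they lay near ENSMUSG00000035253, the zinc finger gene Zfp184 (named from its description), a gene for an uncharacterised protein, Abt1, the butyrophilin gene Btn2a2 and the histone gene Hist1h4h. Enrichment in experiment 1 ran from 8.07-fold to 27.8-fold, and in experiment 2 from 11.04-fold near Abt1 to 66.9-fold near ENSMUSG00000035253. An unshared site of experiment 1 in the same stretch lay 144 bp from the start of a gene described as histone H4a (13.9-fold).

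Among sites with the highest implied background, a pair on chromosome 2 in experiment 2 (98506334 to 98507516 and 98502356 to 98503202) had 1221 and 933 tags at 1.89-fold and 2.24-fold. The FDR multiplied by a site's rank by score came to a whole number, within 0.06, at 156 of the 158 sites of experiment 1 with an FDR under 100% and at 29 of 29 such sites of experiment 2. It was 1 at rank 20 in experiment 1 and 4 at rank 20 in experiment 2.

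The 3 sites inside Klf6 in experiment 1 had a fold of 3.94, 6.01 and 7.83, against a median of 7.17 in that list, so the fold was not low at all 3. Each had many tags for its fold. Plasmid DNA carrying the KLF6 sequence in both libraries could give this. The lowest implied background of the 3 was 21.8 tags per kb against a 95th percentile of 10.6, but that value is tags divided by fold and so restates what drew attention to the sites. Binding of KLF6 to its own gene stays open, as 0 of the 3 sites overlapped a site of experiment 2, whose background at the gene is not given. Of the sites of experiment 1 that scored at least as high as the lowest-scoring of the 3 (score 113.54), 59.8% were shared. The lists do not give the coverage of exons and introns that would tell these apart.

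The overlap of the experiments was weighed against chance and against repeats. Chance overlap from regional density was excluded, since placements moved by 10 to 100 kb reached at most 3 overlaps against 109 observed. Repeats or copy gains stay open, because the implied background divides by the fold, which is higher at shared sites, so that its lower value there in experiment 1 (log2 difference −0.37 per kb, permutation p = 1e-05, and −0.18 per site, permutation p = 0.0302) decides nothing. In experiment 2 the differences were −0.02 per kb (permutation p = 0.804) and −0.03 per site (permutation p = 0.698), and of the 5% of sites with the highest implied background 26.7% were shared there (Fisher's exact test, p = 0.00823) and 18.4% in experiment 1 (p = 0.482), so repeats may account for part of the overlap. Binding of the tagged protein and signal that any precipitation would give at these places remain open, as no precipitation without the tagged protein was among the samples.

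Genes near sites of experiment 1 often had a tRNA gene among their 5 neighbours on either side in the reference gene order. This held for 30 of 255 protein-coding genes against 7.95 expected from 10000 draws of genes of the same chromosomes (permutation p = 0.0001, the smallest the draws can give), which argues against a chance choice of single genes, and for 13 of 343 against 10.4 in experiment 2 (permutation p = 0.2436). The draws did not keep the clustering of the genes. Abt1, Btn1a1, Btn2a2 and Hist1h4h, for example, lay in the stretch of chromosome 13 described above, so the p-value of experiment 1 may be too small. Stretches rich in small genes of any kind could be part of it. The outcome set beforehand for this was an excess of snoRNA genes with permutation p under 0.05. That outcome was met, with an snoRNA gene close to 55 genes against 41.4 expected (permutation p = 0.0128). The remaining kinds were mixed, with an snRNA gene close to 52 against 42.3 (permutation p = 0.0564) and a miRNA gene close to 36 against 48.2 (permutation p = 0.025 for as few). Experiment 2, with no detectable tRNA excess, had snoRNA genes close to 88 against 54.9 (permutation p = 0.0001) and snRNA genes close to 80 against 57.6 (permutation p = 0.0009). Draws that give each gene the same chance may thus be a poor reference for genes near sites, also for tRNA genes. Signal at the tRNA genes themselves is a candidate explanation that the higher fold of these sites is consistent with (log2 difference 0.31, permutation p = 0.0156). Whether this reflects KLF6 or chromatin at genes of RNA polymerase III was not tested, as tRNA gene positions in build mm9 were not at hand.

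Of the 11 sites of experiment 1 within 1 kb of the start of a gene whose symbol the reference places on the same chromosome, 7 were near genes with such a tRNA neighbour: Agbl5, Ctnna3, Fmc1, Ndufs7, Polr3e, Sacm1l and Wbp4. All 7 of these sites were found in experiment 1 alone. The shared sites whose gene had a tRNA neighbour lay more than 5 kb from the start, near Abt1, Btn2a2, Fam71f1, Fam83a, Hes7, Hist1h4h and Rab11a. In experiment 1 the shares with a tRNA neighbour were 14.3% of shared and 9.96% of unshared sites (Fisher's exact test, adjusted p = 0.713), and in experiment 2 they were 13.5% and 1.88% (adjusted p = 0.00509), so the lists leave open whether such sites are shared more often. Chromosome 13 was not the sole source of the difference in experiment 2, where the shares without it were 9.09% and 1.97% (Fisher's exact test, p = 0.0262). In experiment 1 without chromosome 13 both shares were 9.09%. With 2 or 10 neighbours on either side in place of 5, chosen after seeing the data, Fisher's exact test gave p = 0.266 and 0.504 in experiment 1 and p = 3.66e-05 and 0.00291 in experiment 2.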
